A study of Arabidopsis thaliana with 6 samples.

How the data were processed

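Small RNA libraries were made from 6 samples of Arabidopsis Col-0 rosette leaves. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were prepared with an Illumina kit for digital gene expression of small RNA. Mesocosm plants were kept at 24 °C by day and 18 °C by night and sampled after successive selfing generations. The sample labels and growth protocol place them at 21 days and in vegetative growth, while the series text speaks of bolting. Chamber plants had 65% humidity and 16 h of light with 8 h of dark.

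The authors deposited, for each library, a list of distinct sequences of 15 to 36 nt with the raw read count of each. The read trimmer, any filter, the aligner and the genome build are not given in the sources used here. One line of the 810 ppm replicate II list had a header run into a sequence without a count and was left out. Totals ran from 5891305 to 18634475 reads. Reads outside 18 to 28 nt, between 4.52% and 13.3% of a library, were left out, and abundance was computed as RPM, reads per 1000000 reads of 18 to 28 nt.

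Sequences were matched without mismatch to the TAIR10.1 assembly with bwa 0.7.19, and each was given 1 annotation class in a fixed order (rRNA, tRNA, sn/snoRNA, miRNA, TAS, plastid, mitochondrion, then other genes and intergenic). Because the large rRNA subunit is not fully annotated, 4000 bp downstream of nuclear 5.8S genes counted as rRNA. Of 141 listed miRNAs, opposite strands and tasiRNAs, 139 matched a locus of their family and were counted as exact sequences. Sequences shared by several loci, such as miR156a-f, cannot be assigned to 1 locus. Family counts took any 18 to 25 nt sequence holding the core of members of 1 family. Reads of 24 nt with a single match were summed in 1-kb bins. Reads without a perfect match, between 11.4% and 17.6%, have no class.

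Samples were grouped by the growth condition in their labels. CO2 groups were compared with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr, Benjamini-Hochberg adjusted p threshold of 0.05) on the counts of the 4 CO2 libraries, and with DESeq2 1.42.0 as the alternative, in R 4.3.3. Normalised CPM values use TMM factors. The SE of an edgeR log2 fold change was derived from the test, as its size divided by the square root of the F statistic. Log2 values within a replicate number add 0.5 to each count. The 21-nt and 24-nt shares were compared by exact permutation tests. The temperature libraries were compared by RPM ratios with exact intervals at 95% confidence and no test. A count of 0 was read as allowing 3 reads.

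The tests were checked on simulated data drawn from the means of these libraries. At a small spread (dispersion 0.01), the miRNA test recovered 90% of 20 sequences changed 4-fold among 90, the sequence test 78% of 200 among 76338, and the bin test 82.5% of 200 among 12893. At the spread estimated without regard to replicate number, a 16-fold change was recovered for 0%, 0% and 32.5%, and the closing section gives these shares with the number as a block. Biological coefficients of variation were 0.939, 1.32 and 0.627.

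The named sequences followed a rule fixed before the data were examined. For CO2 these were the calls, or the 12 smallest p given as not passing, and the 2 most abundant members of each list. For temperature they were the 12 highest and 12 lowest ratios among sequences with at least 50 RPM in one library, and the 2 most abundant members of each list, at any abundance. The lists covered phase change and flowering, auxin, leaf and meristem, MYB, copper, phosphate, sulfate, NF-Y and GRAS, silencing, tasiRNA, defence, PPR, F-box, young Arabidopsis miRNAs and pollen (miR845). Animal miRNAs served as markers of other material. Alternatives covered scaling, filters, the replicate number as a block, all 6 libraries in 1 fit, each CO2 library left out, family counts, bin width and read denominators. Figures were drawn with matplotlib 3.10.9.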

Results

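Small RNAs of *Arabidopsis thaliana* ecotype Columbia (Col-0), the reference accession, were sequenced from rosette leaves grown under contrasting CO2 concentrations or temperatures. The 6 libraries comprised 2 from plants kept at 430 ± 50 ppm CO2, 2 from plants kept at 810 ± 50 ppm CO2, 1 from plants grown at 22 ± 0.5 °C and 1 from plants grown at 28 ± 0.5 °C. The CO2 plants grew in naturally lit mesocosms, and each of their libraries was a pool of 100 leaves. The temperature plants grew in chambers with 16 h of light and were sampled at bolting. The libraries held 5620256 to 16149639 reads of 18 to 28 nt. At 430 ppm, replicate I had 6488584 and replicate II 16149639. At 810 ppm, replicate I had 6250946 and replicate II 11486408. The 22 °C library had 7322028 and the 28 °C library 5620256. Abundance is given in RPM, the reads per 1000000 reads of 18 to 28 nt, or for the CO2 groups in CPM scaled by TMM factors. The labels do not say what the replicate numbers stand for, so p-values measure only the spread between these samples, which may be technical. Intervals cover counting error only.

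The first comparison asked which size classes made up the small RNA population at each CO2 concentration. Reads of 21 nt, the length of most plant miRNAs, made up 24.7% ± 8.89 (SD, n = 2) of the 18 to 28 nt reads at 430 ppm and 21.8% ± 7.54 (SD, n = 2) at 810 ppm. Reads of 24 nt, the length of siRNAs that direct DNA methylation, made up 25.6% ± 8.53 (SD, n = 2) at 430 ppm and 24.7% ± 13.2 (SD, n = 2) at 810 ppm. Both differences were smaller than the spread between replicates (exact permutation test, two-sided, p = 0.667 for 21 nt and p = 1 for 24 nt, with 0.333 the smallest p that 2 against 2 can give). The 21-nt share at 810 minus 430 ppm was -3.87 percentage points in replicate I and -1.96 in replicate II. With rRNA, tRNA, snRNA and snoRNA reads left out, it was -3.54 in replicate I and 0.80 in replicate II. The 24-nt difference was 2.45 percentage points in replicate I and -4.09 in replicate II. The sign of the 21-nt difference turned without 430 ppm replicate I, at 3.37 percentage points, and without 810 ppm replicate II, at 2.42. The 24-nt difference likewise turned to 5.21 and 8.48 without those libraries.

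**Figure D1:**
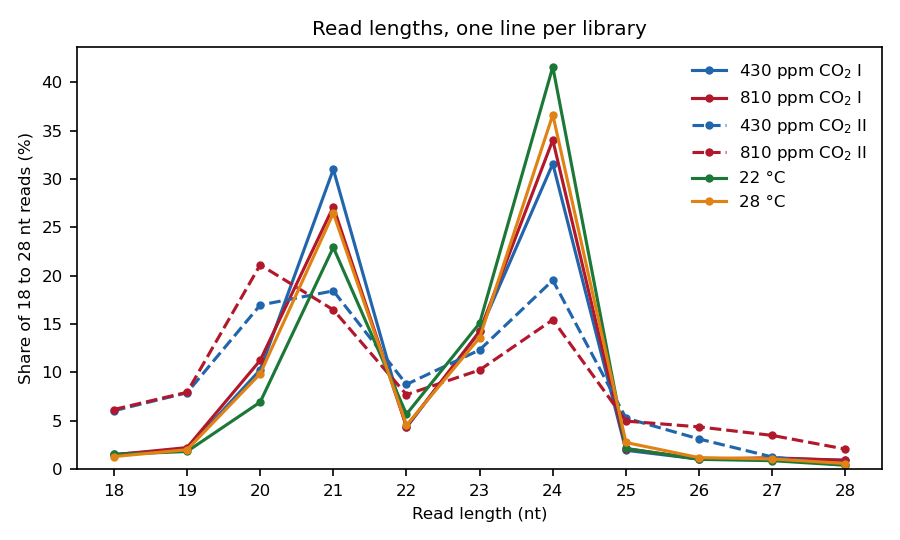
Share of the 18 to 28 nt reads (y axis, percent) at each read length (x axis, nt), with one line per library; solid lines are replicate I or single libraries and dashed lines replicate II. The 24-nt share runs from 15.4% in 810 ppm replicate II to 41.6% at 22 °C, and both replicate II libraries have more reads of 18 to 20 nt than the others.

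Libraries of replicate II differed from those of replicate I in RNA class at both CO2 concentrations. Fragments of rRNA took 39.0% of the reads in 430 ppm replicate II and 40.5% in 810 ppm replicate II, against 5.57% and 5.51% in replicate I. Fragments of tRNA took 16.8% and 19.9% in replicate II, against 4.83% and 7.33% in replicate I. Reads from annotated miRNA loci took 12.5% at 430 ppm and 11.1% at 810 ppm in replicate II, against 28.98% and 23.7% in replicate I. Reads from TAS loci, the sources of trans-acting siRNAs, took 0.283% and 0.253% in replicate II, against 2.30% and 1.91% in replicate I. At 810 ppm the share of tRNA was larger, and those of miRNA and TAS loci smaller, than at 430 ppm in both replicate numbers. The exact permutation p was 0.667 or 1 for every class, but it cannot go below 0.333 with 2 against 2, so it decides nothing. Group means and spreads for 430 and 810 ppm were, for rRNA, 22.3% ± 23.6 (SD, n = 2) and 22.99% ± 24.7 (SD, n = 2), and for tRNA 10.8% ± 8.48 (SD, n = 2) and 13.6% ± 8.86 (SD, n = 2).

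**Figure D2:**
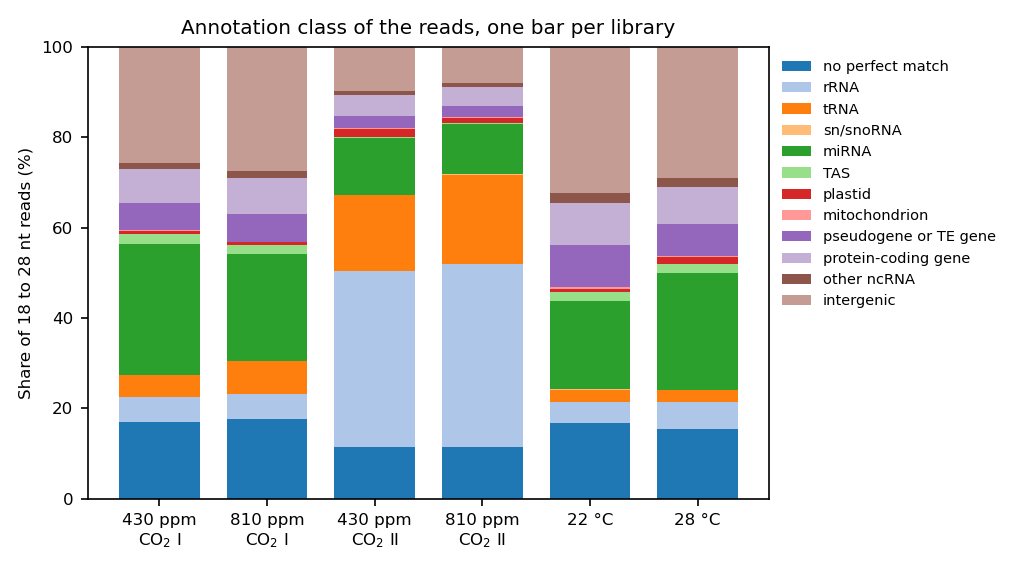
Share of the 18 to 28 nt reads (y axis, percent) in each annotation class, assigned from perfect matches to the genome, with one stacked bar per library. The rRNA part is 39.0% and 40.5% in the replicate II libraries, against 5.57% and 5.51% in replicate I.

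The next comparison asked which miRNAs differed between 810 and 430 ppm CO2. The fit had no term for the replicate number. With that term some sequences passed the threshold, and the closing section gives them. None of the 90 tested sequences passed the threshold in edgeR's quasi-likelihood test, 0 had an unadjusted p under 0.05, and DESeq2 also called 0 with 1 at an unadjusted p under 0.05. The smallest p belonged to miR157a-c, which targets SPL transcription factors of the juvenile to adult transition. It had 37042 ± 9652 normalised CPM (SD, n = 2) at 430 ppm and 21665 ± 1879 (SD, n = 2) at 810 ppm, a log2 fold change of -0.77 ± 0.35 (SE). Its log2 values were -0.93 in replicate I and -0.57 in replicate II. miR157d, the 20-nt sequence of miR157a-c without its first base, had a log2 fold change of -0.91 ± 0.62 (SE). Its values were -0.99 in replicate I and -0.79 in replicate II. It matches the MIR157a, MIR157b, MIR157c and MIR157d loci, so its reads cannot be told from shorter forms of miR157a-c.

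Among the other sequences with the smallest p, miR396a-3p, the strand opposite a regulator of GRF growth factors (TAIR10.1 chromosome 2, 4142331 to 4142351, in the MIR396a gene AT2G10606), had -2.55 ± 1.26 (SE). Its values were -2.15 in replicate I and -2.64 in replicate II. miR827, a phosphate-starvation miRNA that targets NLA (chromosome 3, 22122811 to 22122831, in MIR827, AT3G59884), had -2.04 ± 1.26 (SE), with -2.25 and -1.14. miR161.1, a regulator of PPR genes, had -1.11 ± 0.86 (SE) and miR158a -0.54 ± 0.44 (SE), both negative in each replicate number. Positive values in both replicate numbers were found for miR168a-b, which targets AGO1, at 0.67 ± 0.42 (SE), for miR156h at 1.75 ± 1.25 (SE) and for miR156g at 0.98 ± 0.85 (SE). miR319a-b, which targets TCP transcription factors, had 2.07 ± 2.15 (SE), and its values were 0.48 and 2.12. For miR780 the value of 3.09 ± 3.30 (SE) rested on replicate II, since both replicate I libraries had 0 reads, which allows up to 0.462 RPM at 430 ppm and 0.480 at 810 ppm. miR840 had -1.37 ± 1.28 (SE), with 0.25 in replicate I and -2.18 in replicate II.

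**Figure D3:**
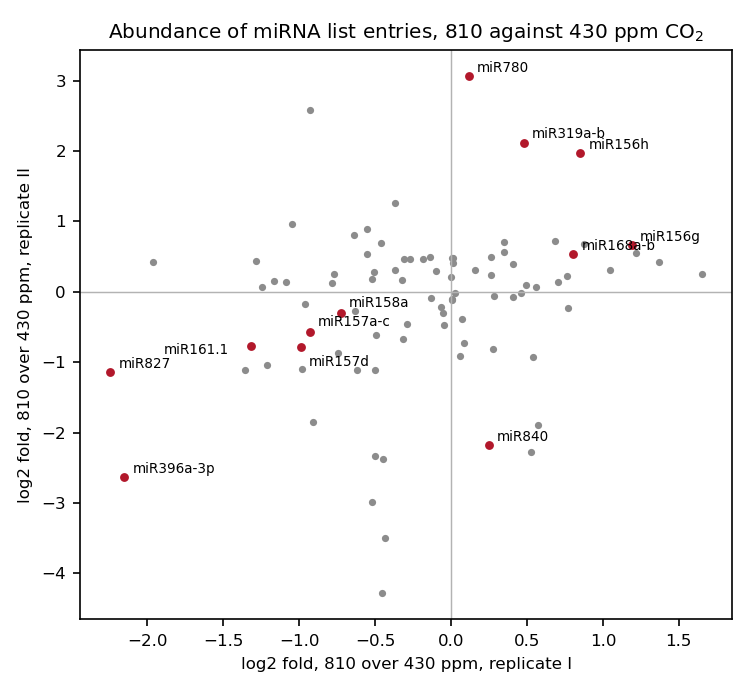
Log2 fold of 810 over 430 ppm CO2 for each of the 90 tested miRNA list entries, within replicate I (x axis) and within replicate II (y axis); the 12 entries with the smallest p are red and named. No entry passed the test, which had no term for the replicate number, and 52 of the 90 lie on the same side of 0 in both replicate numbers.

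In the fit without a term for the replicate number, no list of miRNAs fixed in advance held a call. This was so over all sequences tested and when adjusted over the list alone. With that term, the calls included miR157a-c of the phase change and flowering list, and miR396a-3p and miR319a-b of the leaf and meristem list. The closing section gives them. All 5 tested members of the phosphate list had negative values and 4 were negative in both replicate numbers. The median log2 fold change was -0.88, and miR399b-c was at -0.05. That median was the value of miR399c-5p, which lay near the floor. It had 0.920 and 0.337 normalised CPM at 430 ppm, and 0.635 and 0 at 810 ppm. In 810 ppm replicate II, miR399f and miR399a had only 0.156 and 0.623. The phase change and flowering list had 4 positive and 6 negative values, and miR156a-f had -0.25 ± 0.93 (SE). The auxin list had 8 positive and 2 negative values, with miR167a-b at 0.09 ± 0.37 (SE) and miR390a-b at 0.48 ± 1.01 (SE). In the leaf and meristem list, 5 were positive and 6 negative, with miR166a-g at -0.16 ± 0.53 (SE) and miR164a-b at 0.33 ± 1.00 (SE). The copper list had 4 positive and 1 negative, with miR408 at 0.49 ± 1.35 (SE) and miR408-5p at 0.32 ± 1.60 (SE), the latter 0.57 in replicate I and -1.90 in replicate II. The PPR list had 5 negative values, of which 2 were negative in both replicate numbers, while miR161.2, at -0.33 ± 0.71 (SE), was -0.77 in replicate I and 0.25 in replicate II. TAS1-siR255, a TAS1 siRNA in that list, had -1.05 ± 2.12 (SE), with 118 ± 160 normalised CPM (SD, n = 2) at 430 ppm. The list of young Arabidopsis miRNAs had 6 positive and 15 negative values, of which miR391 was -0.08 ± 0.96 (SE). Positive and negative values numbered 4 and 3 in the NF-Y and GRAS list, 2 and 3 in the silencing list, 4 and 2 in the tasiRNA list, 3 and 0 in the F-box list and 2 and 0 in the MYB list. The most abundant members of these lists, apart from those already named, were miR171a at 0.50 ± 0.90 (SE) and miR169d-g at 0.46 ± 1.21 (SE) in the NF-Y and GRAS list, and miR162a-b, which targets DCL1, at -0.32 ± 0.82 (SE) in the silencing list. miR173 of the tasiRNA list had 0.16 ± 0.78 (SE), while miR169d-g and miR173 were negative in replicate I and positive in replicate II. In the F-box list, miR393b-3p had 0.44 ± 0.75 (SE) and miR394a-b 0.79 ± 1.78 (SE), the latter -0.55 in replicate I and 0.90 in replicate II. In the MYB list, miR159a had 0.05 ± 1.31 (SE), with 0.46 and -0.02 within the replicate numbers, and miR159b 0.17 ± 1.21 (SE). The sulfate and defence lists had 1 tested member each, miR395b,c,f at 0.34 and miR825 at -0.41. The remaining members that the naming rule picked, miR395a,d,e, miR472, miR845a and miR845b, were not abundant enough to test. In counts simulated at the spread that this fit estimated, its test recovered 0% of sequences changed 16-fold.

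Without regard to annotation, and again with no term for the replicate number, edgeR called 0 of 76338 distinct sequences, with 42 at an unadjusted p under 0.05, and DESeq2 called 0. Unique 24-nt reads were also summed in 1-kb bins of the nuclear genome. In a fit of the same form, edgeR called 0 of 12893 bins, with 122 at an unadjusted p under 0.05. DESeq2 called 71 bins, and all 71 were higher at 810 ppm. With a term for the replicate number, edgeR called some sequences and bins, which the closing section gives.

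The temperature comparison asked which miRNAs differed between 28 and 22 °C. With 1 library each it has no replicate check. Of 43 sequences with at least 50 RPM in one library, 8 were at least 2-fold higher at 28 °C and 2 at least 2-fold lower. The highest ratio was that of miR157a-3p, the strand opposite miR157, with 43.7 RPM at 22 °C and 444 at 28 °C, a ratio of 10.2 (95% exact interval 9.05 to 11.5). miR156a-f, which targets SPL genes, had 11807 and 35481 RPM, a ratio of 3.01 (2.98 to 3.03). miR157d had a ratio of 2.81 (2.74 to 2.87), while miR157a-c was at 1.31. miR165a-b, a regulator of HD-ZIP III genes of leaf polarity, had a ratio of 2.82 (2.73 to 2.90) and miR166a-g, of the same target group, 1.80. Ratios above 2 were also found for miR408-5p, from a copper-responsive locus (chromosome 2, 19319866 to 19319886, in MIR408, AT2G47015), at 3.24, for miR396b-3p at 2.70, for miR393b-3p at 2.67 and for miR390a-b, the trigger of TAS3 siRNAs, at 2.18. Of these, miR408-5p, miR396b-3p and miR393b-3p are strands opposite the guide. The 2 sequences on the other side were miR156h, 2.92-fold lower at 28 °C (2.43 to 3.52), and miR827, 2.02-fold lower (1.75 to 2.34).

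**Figure D4:**
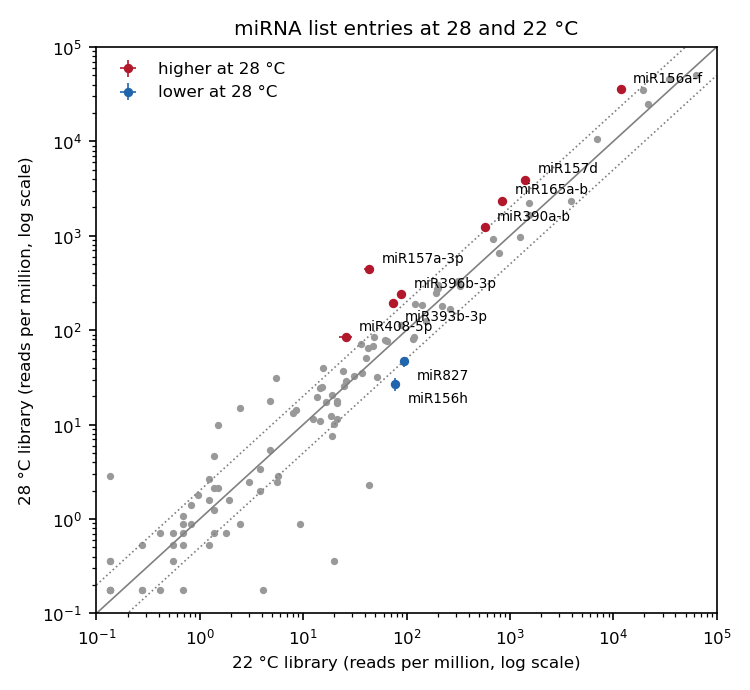
Abundance at 22 °C (x axis, RPM, log scale) and 28 °C (y axis, RPM, log scale) of the miRNA list entries seen in both libraries; the solid line marks equal values, dotted lines a ratio of 2, and bars on coloured points exact 95% Poisson intervals. The 8 red entries are at least 2-fold higher and the 2 blue ones at least 2-fold lower at 28 °C, among entries with at least 50 RPM in one library.

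Smaller differences made up the rest of the sequences picked by size. At 28 °C, miR172a-b, which targets AP2-like floral regulators, was 1.69-fold lower, miR775 1.61-fold, miR822 1.59-fold, miR843 1.42-fold and miR824 1.40-fold. miR173, the trigger of TAS1 and TAS2 siRNAs, was 1.28-fold lower, miR167a-b 1.24-fold, miR164c 1.24-fold, miR162a-b 1.22-fold and miR161.2 1.18-fold. Ratios between 1.5 and 2 were found for miR167a-3p at 1.94, miR161.1 at 1.74 and miR172b-5p at 1.54. By list, only members with at least 50 RPM in one library were counted. Of these, 3 of 7 phase change members were higher and 1 lower by the 2-fold rule. Among auxin members 2 of 8 were higher, and among leaf and meristem members 2 of 7. The remaining counted members of these lists were under 2-fold. The tasiRNA list had 1 of 4 higher. None of 6 young miRNAs, 4 silencing, 3 NF-Y and GRAS, 3 PPR or 2 MYB members reached 2-fold, with miR158a at 1.16, miR391 at 1.08, miR168a-b at 1.52, miR168a-3p at 1.54, miR169a at 1.41, miR169d-g at 1.18, miR159a at 1.06, miR159b at 1.28 and TAS1-siR255 at 0.894. miR164a-b, of the leaf and meristem list, was at 1.46. The copper, F-box and phosphate lists had 1 member each at 50 RPM or more, which were miR408-5p, miR393b-3p and miR827, and the sulfate, defence and pollen lists had none. Below that minimum, miR399b-c of the phosphate list had 35 reads at 22 °C and 99 at 28 °C, a ratio of 3.69 (2.48 to 5.58), and miR408 107 and 138 reads, a ratio of 1.68 (1.30 to 2.18). The guide miR393a-b, not picked by the naming rule, went the other way from miR393b-3p. It had 41 reads at 22 °C and 14 at 28 °C, a ratio of 0.445 (0.224 to 0.833). The intervals of miR825 at 0.804 (0.616 to 1.04), miR394a-b at 0.762 (0.548 to 1.05), miR395b,c,f at 0.884 (0.467 to 1.64), miR395a,d,e at 0.401 (0.0952 to 1.30) and miR472 at 1.42 (0.574 to 3.55) all included 1. miR845a had 1 read at 22 °C and 0 at 28 °C, and miR845b 0 in both.

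Scaling changed the balance of these counts. The median log2 ratio of the 43 sequences was 0.38, and TMM factors over the miRNA list moved every ratio by -0.45 on the log2 scale. Under TMM, 5 sequences were at least 2-fold higher and 5 lower. By that shift, miR396b-3p, miR393b-3p and miR390a-b fell under 2-fold, and miR172a-b, miR775 and miR822 became at least 2-fold lower. Scaled to the reads of the miRNA list, 10 were higher and 11 lower, and every ratio moved by -0.36 on the log2 scale. These are out of 70 sequences in place of 43, since more reach 50 RPM on that scale. A sequence with a log2 ratio between 0 and the size of such a shift changes sign by construction, and among those named here these were miR157a-c, miR159a, miR159b, miR169d-g, miR158a and miR391. The same 2-fold rule separated 28 of 37 sequences between the replicates of 430 ppm and 21 of 36 between those of 810 ppm, more than the 10 of 43 between the temperatures. Between 810 and 430 ppm libraries of the same replicate number it separated 8 of 37 in replicate I and 1 of 27 in replicate II.

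Size and class also differed between the single temperature libraries. The 24-nt share was 41.6% (95% Wilson interval 41.58 to 41.65) at 22 °C and 36.7% (36.62 to 36.70) at 28 °C. The 21-nt share was 22.9% (22.90 to 22.96) at 22 °C and 26.5% (26.44 to 26.51) at 28 °C. Reads from miRNA loci took 19.6% and 25.9%, and rRNA fragments 4.66% at 22 °C, with a ratio of 1.29 at 28 over 22 °C. These intervals compare the libraries, not the conditions.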

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

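Sequences of 8 animal miRNAs, fixed as markers before the data were examined, lie outside the comparisons and were seen above the 3 reads that a count of 0 allows in 4 libraries. Their reads numbered 25 in 430 ppm replicate I, 29 in 810 ppm replicate I, 32 at 22 °C and 42 at 28 °C, which is 3.85, 4.64, 4.37 and 7.47 RPM. In 430 ppm replicate II they numbered 0, which allows up to 0.186 RPM, and in 810 ppm replicate II 1. No outlier test applied, since no group had 4 libraries.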

How the results depend on the processing

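The results below used alternatives fixed before the data were examined, except the use of all annotated mature sequences, which was added afterwards. The fits other than the replicate block had no term for the replicate number. At the spread that the main miRNA fit estimated, its test recovered 0% of miRNAs changed 16-fold in simulated counts. A count of 0 miRNA calls without that term therefore says little about stability. The count of miRNA calls stayed at 0 with library totals, DESeq2, all 6 libraries, no filter, family counts, all annotated mature sequences and each CO2 library left out. Sequence and bin calls also stayed at 0 under their alternatives, apart from 71 bins with DESeq2 and the fits with a replicate block; the cause of the 71 was not tested.

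The replicate block gave 4 miRNAs, 99 sequences and 145 bins past the threshold, where 144 bins were higher at 810 ppm and 1 lower. All 71 bins called by DESeq2 were among the 145, in fits to the same libraries. The 4 miRNAs were miR157a-c (log2 fold change -0.75), miR396a-3p (-2.42), miR319a-b (1.74) and miR780 (3.04). In replicate I, miR780 had 0 reads at both concentrations, and miR319a-b had 0.251 normalised CPM at 430 ppm and 0.363 at 810 ppm. Both calls therefore rest largely on replicate II, with 1 library at each concentration. The labels do not say that the number pairs libraries, so this is not a paired design by label, though deviations of replicate I from II correlated between the CO2 groups at 0.887 across miRNAs, 0.923 across sequences and 0.827 across bins. The block lowered the miRNA coefficient of variation from 0.939 to 0.304. In counts simulated at its own spread, the blocked test recovered 40% of 20 miRNAs changed 4-fold among 90, and 100% of miRNAs, 44% of sequences and 93% of bins changed 16-fold.

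The 21-nt difference of -2.92 percentage points became 0.20 over distinct sequences, and ranged from -9.20 to 3.37 with a library left out, positive at 3.37 without 430 ppm replicate I and 2.42 without 810 ppm replicate II. The 24-nt difference of -0.82 became 0.26 with rRNA, tRNA, snRNA and snoRNA reads left out, and ranged from -10.1 to 8.48, positive at 5.21 and 8.48 without those same libraries. Leaving a library out unbalances the replicate numbers, whose shares lay far apart. At 430 ppm, replicate I and II had 31.0% and 18.4% of 21 nt, and 31.6% and 19.5% of 24 nt. The cause of the changes under the other settings was not tested. The 10 miRNAs at least 2-fold apart between temperatures became 21 scaled to the reads of the miRNA list and 17 at a minimum of 10 RPM, where more sequences qualify, 70 and 69 in place of 43. TMM gave 10, and family counts gave 8, of which 8 were higher at 28 °C and 0 lower. Without replication at 22 and 28 °C, depth bounds counting error alone.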

Other observations

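All tests and bin thresholds in this part were chosen after the result was seen, apart from the search for reads of other lengths and the tests on rRNA fragments. Below the abundance minimum, 2 floral and leaf regulators and a young miRNA differed between the temperature libraries. miR780 (chromosome 4, 8504166 to 8504186, in MIR780, AT4G14811) had 147 reads at 22 °C and 2 at 28 °C, a ratio of 56.4 (95% interval 15.3 to 470.2). miR172c-d had 314 and 13 reads, a ratio of 18.5 (10.7 to 35.2), and miR319a-b had 69 and 5. In the other direction miR396a-3p had 18 reads at 22 °C and 84 at 28 °C, and miR848 had 40 and 174. These were named after their values were seen.

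Some 24-nt siRNA bins were present at 810 ppm and without a read at 430 ppm. With at least 5 reads per 1000000 unique 24-nt reads in both 810 ppm libraries and at most 0.5 in both 430 ppm libraries, 28 bins met the rule, 0 met its reverse, and the crossed splits of the 4 libraries gave 1 and 1, while the splits by replicate number gave 60 and 112. Within replicate I alone 124 bins met the rule and 49 its reverse, and within replicate II 203 and 438. The bins held 656 and 622 reads at 810 ppm and 0 and 0 at 430 ppm, from totals of 1121924, 645299, 1093448 and 1119865 unique 24-nt reads. The counts of 0 follow from the rule, since 0.5 per 1000000 is less than 1 read at the 430 ppm totals. They lay on 5 chromosomes, 16 touching an annotated gene and 12 none. Examples were chosen after their values were seen. On chromosome 1, the bin 4720001 to 4721000, at AT1G13760, had 39 and 16 reads at 810 ppm. On chromosome 3, the bin 8509001 to 8510000, at HGL1 and AT3G23645, had 69 and 38. The absence held for single bins, not for whole clusters. The next bin on chromosome 3, 8510001 to 8511000, had 2 and 25 reads at 430 ppm against 140 and 206 at 810 ppm. Bins called with the replicate block also included differences of degree. On chromosome 4, the bin 13902001 to 13903000 had 54 and 222 reads at 430 ppm against 485 and 1920 at 810 ppm. The counts were 43, 15 and 48 with at least 3 or 10 where present or at most 1 where absent, and 9, 0 and 1 for the reverse.

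The same bins separated the temperature libraries, which share no library with the CO2 comparison. All 28 had at least 5 on that scale at 22 °C (3790 reads) and 1 did at 28 °C (31 reads). Of the 71 bins DESeq2 called higher at 810 ppm, 71 were higher at 22 than at 28 °C, with medians of 226 and 5.12, against 50.3% of all bins with at least 40 reads. That share takes bins whatever the size of their difference. By the limits of 5 and 0.5, 286 bins were present at 22 °C and absent at 28 °C, and 10 the reverse. The direction was thus common among bins that differed strongly between the temperature libraries. Across 7777 bins, which are not independent replicates, 810 minus 430 ppm correlated with 22 minus 28 °C at r = 0.54 (rho = 0.18), with r = 0.32 and rho = -0.04 in replicate I. Across 72 miRNAs r was 0.29 (rho = 0.16) over both replicate numbers, -0.10 in replicate I and 0.49 in replicate II.

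For these bins, reads carried over from the 22 °C library are argued against. At the share the bins imply, 9 short sequences particular to that library would give 180 reads in 810 ppm replicate I and 170 in replicate II. The observed reads were 15 and 30, or 0.0835 and 0.176 of those expected. A deletion in the 430 ppm plants stays open for the bins without reads of other lengths there. Such reads with a single match reached 9 of the 28 bins at 430 ppm, and a deletion of a whole bin would leave none. They were few, with 5 in replicate I and 13 in replicate II. At 28 °C they reached only 7 bins, so their lack in the other bins decides nothing. A share of flowers or pollen also stays open, because the markers miR845a and miR845b gave 4 reads in the 810 ppm and 22 °C libraries together. The CO2 concentration itself stays open and was not tested, and it is not the contrast between the 22 and 28 °C libraries, where the same bins also differed.

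The replicate II libraries had more rRNA and tRNA. Dilution alone is argued against, because it would move every miRNA by 1 factor, and log2 of II over I had an SD of at least 1.52 across 44 entries against 0.70 and 0.65 for 810 over 430 ppm. A capture bias with GC content could not be decided, with r = 0.17 across 35 guides (permutation p = 0.330), which are not independent replicates. Library preparation and differences between the sampled plants cannot be told apart, since nothing in the labels says how replicate numbers were made.

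Abundant guides had their last base read as G more often at 430 ppm, in 7 of 8 scored guides in both replicate numbers, with medians of 0.295% and 0.172% against 0.0357% and 0.0126% at 810 ppm. The guides of 20 nt lacked an excess of this size, since miR156a-f had 0.0210% and 0.0017% at 430 ppm against 0.0357% and 0.0067% at 810 ppm, and miR158a had 0.0374% and 0.0265% against 0.0358% and 0.0198%. An error at the last base of inserts of every length is argued against, since 10% of 20 rRNA fragments showed it, with 25% expected by chance. A miscall at read position 21 stays open. The only 21-nt fragment among them had 0.280% and 0.115% at 430 ppm against 0.0655% and 0.0135% at 810 ppm. Among 46 rRNA fragments of 22 nt or more, 52.2% had G at position 21 more often at 430 ppm in both replicate numbers, with 25% expected by chance. Pooled over rRNA fragments of 24 nt or more, G at position 21 was 0.155% and 0.134% at 430 ppm and 0.0652% and 0.0167% at 810 ppm, while at position 22 it was 0.0614% and 0.00451% against 0.0693% and 0.0035%, and at positions 18, 19, 20 and 23 it was higher at 810 ppm in both replicate numbers, a comparison made after the guides were seen.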
